A study of Homo sapiens with 12 samples.

How the data were processed

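RNA sequencing was performed by the authors on 12 libraries of IMR90 induced pluripotent stem cell cultures, 3 per group, carrying GATA6-AS1 or control shRNA, at differentiation days 2 and 5. Per the labels' protocols, polyA RNA was made into libraries with the Illumina TruSeq RNA kit and sequenced on an Illumina HiSeq instrument as 75 bp paired-end reads. Groups were taken from the sample titles. HTSeq, DESeq2 and R 3.4.0 and the genome GRCh38 are listed in the submitters' processing notes, with no role or order. The aligner, annotation, normalization and filter were not given in the sources used here.

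The values analysed were 2 tables of the authors' own comparison, 1 per day. Each row held a gene symbol, the difference AK minus Ctrl and, per the file headers, an unadjusted p-value on day 2 or its −log10 on day 5. The differences deposited by the authors were read as log2 values, since they lay within 11 of 0 for all genes. The headers name neither scale nor base, so this reading is an assumption. Which tool gave the differences and p-values is not given in the sources used here: the headers speak of a difference of status, and the smallest p was 1.11e-08 although differences reached -10.74, so the p-values deposited by the authors are not described here as those of DESeq2. Further, 175 day 2 genes and 341 day 5 genes had exactly the difference and p of another gene, in sets of up to 47 and 48 genes, as genes with few reads would; their differences were at most 1.20 and 0.73 in size. AK was taken as the GATA6-AS1 shRNA arm because the control was coded Ctrl and each day had only these arms. The −log10 values deposited for day 5 were turned back into p-values. Counts, totals per library and replicate values were not analysed here, so depth is unknown and no standard error, replicate check or refit could be computed.

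Both tables listed only genes up to a largest p, 0.00672 on day 2 and 0.0128 on day 5. The design written before the data were examined called genes by the authors' adjusted p under 0.05. The tables analysed give no adjusted p, so every listed gene was used as called. The largest p listed is what a Benjamini-Hochberg limit of 0.05 would give over 26745 genes on day 2 and 27907 on day 5, so the listing can itself be an adjusted p under 0.05, though the rule is not given in the sources used here. As a stricter check on the authors' p-values, a Benjamini-Hochberg bound was computed over 62700 annotated genes with the unlisted ones at a p of 1, and 1784 day 2 genes and 4515 day 5 genes had a bound under 0.05. The largest bound was 0.117 on day 2 and 0.112 on day 5. This bound assumes that all annotated genes were tested, so a gene failing it can still have passed the authors' own limit. Genes not listed were treated as not having passed, never as unchanged.

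Gene lists, 27 in all with 673 distinct genes, were fixed before the data were examined. They covered the target locus, developmental lineages, cardiac muscle, signalling pathways, matrix, cell cycle, stress, interferon, metabolism and retinoic acid. For lists with at least 4 listed members, higher against lower was compared with the other listed genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists tested that day. This test treats genes as independent, which co-regulated genes are not, so its p-values are too small to an unknown degree. It compares direction only, because the full set of genes tested is unknown. The test was tested on simulated data made from the 7172 day 5 genes: of 300 lists of 20 genes with 90% planted 1 way, 100% were recovered in either direction, and 3.33% of unplanted lists were called. Recovery was counted at an unadjusted p under 0.05, so it overstates what the adjusted test can find. Nearly all day 2 lists also had fewer than 20 listed members.

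For genes listed on both days, direction was compared by Fisher's exact test and differences by Spearman's rho with 100000 permutations. These tests and the exact intervals also treat genes as independent, so p-values are too small and intervals too narrow to an unknown degree. A gene with opposite directions was called different between days at the larger of the authors' p-values, which needs no assumption on the spread. The named genes were GATA6-AS1 and GATA6, the 6 highest and 6 lowest with a current symbol each day, up to 3 members with the smallest p of each list with at least 3 listed, and the 4 with the smallest larger p in each combination of directions. A planned minimum mean count of 50 could not be applied without counts. The rule gave 90 genes on day 2 and 91 on day 5, of which the text names most, and a few are not reported here; genes named outside it are said to have been picked after their values were seen.

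Symbols were matched to GENCODE 44 directly or through synonyms, for 3269 day 2 genes (91.0%) and 6164 day 5 genes (85.9%). Most unmatched symbols were older clone names. On each day 7 symbols were dates, as a spreadsheet makes them, and were left out of named genes and lists. GC content was that of the longest coding transcript. Alternatives were adjusted p bounds of 0.05, 0.01 and 0.001, a minimum size of 1, coding genes only, day 2's largest p applied to day 5, a list mean tested against 20000 random lists, members of 1 list only, genes sharing no values with another, genes outside protein synthesis families, epithelial and mesenchymal markers of the transition list apart, and tests within 5 bins of GC content. Genes with near-identical copies, such as TDGF1, MYH6 with MYH7, SET and ribosomal protein genes, are uncertain, since the counting rule for shared reads is not given in the sources used here. Computation used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.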

Results

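The data collected were messenger RNA profiles of human cells early in cardiac differentiation. IMR90 induced pluripotent stem cells, an established line reprogrammed from lung fibroblasts, had received a lentiviral short hairpin RNA (shRNA) against GATA6-AS1 or a control shRNA. GATA6-AS1 is a long noncoding RNA transcribed divergently from GATA6, which encodes a zinc finger transcription factor of heart and endoderm. The 12 libraries formed 4 groups of 3, control and knockdown at differentiation day 2 and the same at day 5. The values analysed were the authors' own comparison of knockdown with control at each day, given as a difference and a p-value per gene. Sequencing depth and values per library are unknown here, and the labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples. Differences are knockdown minus control and were read as log2 values, a reading that the column headers leave open. A gene is described as having risen or fallen where the authors' deposited table lists it, since each table holds only genes under a largest p.

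The targeted locus was read first at each day. GATA6 rose on day 2, with a log2 difference of 0.85 (p = 0.00120) in the authors' deposited table. By day 5 it had fallen, with a log2 difference of -1.95 (p = 1.47e-06) in the authors' deposited table. GATA6-AS1 itself had no entry under that symbol on either day. An entry under an older clone name is not excluded, since 323 day 2 and 1008 day 5 symbols were unmatched. The knockdown was therefore not measured by the values analysed here, and the group labels were not checked by their target. In GENCODE 44 on GRCh38, GATA6 spans chromosome 18, 22169589 to 22202528, on the plus strand, and GATA6-AS1 spans 22164886 to 22169878 on the minus strand. The genes overlap by 290 bp, and the library kit named in the labels does not mark strand, so reads from that overlap cannot be assigned to either gene.

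The first comparison asked how GATA6-AS1 knockdown changed expression at day 2, when cells pass through primitive streak and early mesoderm stages. Definitive endoderm genes rose together and paraxial and intermediate mesoderm genes fell together. Among the endoderm genes, the authors' deposited table gave log2 differences of 4.39 for HHEX and 3.06 for SOX17, both endoderm transcription factors, the latter picked after its value was seen. FOXC2, TBX6 and RIPPLY2, regulators of presomitic mesoderm and somite formation, had log2 differences of -4.43, -3.72 and -4.47 in the authors' deposited table. In all, 3592 genes were listed, 2085 higher and 1507 lower in knockdown, and the largest p listed was 0.00672.

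Of the 27 definitive endoderm genes fixed before the data were examined, 13 rose, none fell and the rest did not pass the test. Fisher's exact test of direction against the other listed genes gave an adjusted p of 0.0123 over 23 lists, and the median log2 difference was 2.25. FOXA1, a pioneer factor of endoderm, had a log2 difference of 1.79 in the authors' deposited table, and the tight junction gene CLDN6 had 1.87. The epithelial adhesion gene EPCAM stood at 2.75 and the lipoprotein gene APOC1 at 2.25 in the authors' deposited table. Of 25 paraxial and intermediate mesoderm genes, 10 fell and none rose, with a median of -2.87 and an adjusted Fisher's exact p of 0.00382. PAX2, a kidney and intermediate mesoderm factor, fell by 2.29 in the authors' deposited table.

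Primitive streak and mesendoderm genes had 7 higher and 12 lower among 19 listed of 28 (median -1.78, adjusted Fisher's exact p = 0.253). Among differences of at least 1 in size the lean to lower passed (adjusted Fisher's exact p = 0.0197), as it did by list mean against random lists. WNT3A, a streak-inducing WNT ligand, had a log2 difference of -3.32 in the authors' deposited table, whereas FGF17 had 4.63. Further streak genes, picked after their values were seen, were TBXT (brachyury) at -4.52, MESP1 at -2.98 and MIXL1 at -1.78 in the authors' deposited table. Cardiac mesoderm and progenitor transcription factors had 4 higher and 7 lower of 36 (adjusted Fisher's exact p = 0.561). In that list FOXC1 was at -2.76 in the authors' deposited table. HAND1, a factor of lateral mesoderm and the left ventricle, was at -3.55 in the authors' deposited table. Cardiac progenitor surface and signalling genes were 5 higher and 5 lower of 20. Among them PDGFRA, a receptor of cardiac progenitors, was at -3.31 and the WNT enhancer RSPO3 at -4.96, against 1.85 for N-cadherin (CDH2), in the authors' deposited table.

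The sarcomere and contractile protein list was barely represented at day 2, with 3 of 44 listed, all higher. These were TPM1 at 0.58, TNNT1 at 0.55 and ENO3, a muscle enolase and not a sarcomere protein, at 1.09 in the authors' deposited table. Only TPM1 passed when adjusted over the list alone. Calcium handling and ion channel genes had 5 higher and 3 lower of 26, among them TRDN, a sarcoplasmic reticulum anchor, at 3.15, GJA5 (connexin 40) at 3.22 and ATP2A2, the SERCA calcium pump, at -0.41 in the authors' deposited table. WNT pathway genes were 8 higher and 8 lower of 51. FZD5 was at 4.89 and FZD8 at 1.54, both receptors, while the nuclear effector LEF1 was at -5.97 in the authors' deposited table. BMP, Nodal and TGF-beta genes were 8 higher and 6 lower of 40, with ID1, a BMP target, at 1.05 and the activin subunit INHBB at -3.67 in the authors' deposited table. FGF and Notch genes were 8 higher and 5 lower of 36, including NOTCH3 at 1.35 and the Notch target HEYL at -2.89 in the authors' deposited table.

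Endothelial and haematopoietic genes were 2 higher and 4 lower of 36. The VEGF receptor FLT1 was at -1.24 and the endothelial factor ERG at -2.07 in the authors' deposited table. All 4 listed neuroectoderm genes of 37 were lower (adjusted Fisher's exact p = 0.178), including ZIC5 at -1.07 in the authors' deposited table. Neural crest genes were 3 higher and 4 lower of 15, and the lower ones included NGFR at -4.29, SNAI2 at -3.11 and TWIST1 at -2.82 in the authors' deposited table. Non-neural ectoderm genes were 3 higher and 1 lower of 20, with claudin gene CLDN7 at 2.45 and the epithelial splicing factor ESRP1 at 1.94 in the authors' deposited table. Trophoblast and amnion genes were 1 higher and 3 lower of 23, and IGFBP5 was at -3.01 in the authors' deposited table. Mesenchyme genes were 3 higher and 6 lower of 30. The epithelial-mesenchymal transition list of 25 holds markers of both sides, which were set apart after the directions were seen. Of its 12 epithelial markers 8 were higher and none lower, and of its 13 mesenchymal markers 1 was higher and 8 lower (Fisher's exact p between sides = 0.000411). The collagen genes COL1A2 and COL5A1 were at -0.96 and -1.41, and PDGFRB, a pericyte receptor, at -1.77 in the authors' deposited table. Extracellular matrix genes were 15 higher and 17 lower of 56, with the laminin gene LAMC1 at -1.12 in the authors' deposited table.

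Cell cycle genes had 2 higher and 9 lower of 30 (adjusted Fisher's exact p = 0.0845). The cyclin-dependent kinase inhibitor CDKN1C, with the smallest p of the day 2 table, rose by 1.50 (p = 5.01e-08) in the authors' deposited table, and the replication genes MCM2 and TYMS were at -0.77 and -0.69. Stress and p53 genes were 6 higher and none lower of 29 (adjusted Fisher's exact p = 0.200), with ATF3 at 1.44 and IER3 at 1.02 in the authors' deposited table. Interferon response genes were 5 higher and 3 lower of 27, including IFITM1 at 2.24 and BST2 (tetherin) at 1.90 in the authors' deposited table. Glycolysis and hypoxia genes were 3 higher and 3 lower of 29, with the peptide hormone gene ADM at 2.29 and hexokinase HK1 at -1.57 in the authors' deposited table. Pluripotency genes were 5 higher and 1 lower of 22, with SALL4 at 0.62 and ZFP42 (REX1) at -0.95 in the authors' deposited table. Retinoic acid genes were 2 higher and 2 lower of 18, with the synthesis enzyme ALDH1A3 at 2.08 and the binding protein CRABP2 at -1.05 in the authors' deposited table. Epicardial genes had 1 higher of 12. The 2 HOX genes of 31 with an entry, HOXA2 and HOXB2, named after their values were seen, had the same difference of -0.50 and the same p in the authors' deposited table as 25 genes in all, so they are not counted here as separate decreases.

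By size, the largest day 2 increases included SLC40A1 (the iron exporter ferroportin) at 5.46, the cation channel TRPA1 at 5.09, FZD5, the cholecystokinin receptor CCKBR at 4.75 and FGF17, in the authors' deposited table. The largest decreases were CDH11 (a mesenchymal cadherin) at -6.13, LEF1, the integrin ITGA8 at -5.85, DCHS2 at -5.81, the protocadherin PCDH19 at -5.71 and the potassium channel KCNK17 at -5.59, in the authors' deposited table. By list mean against random lists, cardiac mesoderm factors, WNT, neural crest, trophoblast and mesenchyme genes also passed as lower (adjusted permutation p from 0.00115 to 0.0418). Of the 245 list entries found on day 2, 243 passed when adjusted over the list alone and 166 when adjusted over all annotated genes. The count for the list alone was nearly fixed in advance, because only genes with a p up to 0.00672 were listed. These entries hold 198 distinct genes. The endoderm call ended when only differences of at least 1 in size were used (adjusted Fisher's exact p = 0.119) or only members of 1 list (adjusted Fisher's exact p = 0.109). At that size only GATA6 (0.85) left the listed endoderm genes and none was lower, while 68.5% of all genes kept were higher. The paraxial call ended among genes with an adjusted p under 0.05 (adjusted Fisher's exact p = 0.0942), and both lists had too few members left for a call at a bound of 0.01, as had paraxial mesoderm with members of 1 list only. Direction also followed GC content on day 2, with 44.4% of coding genes higher in the lowest of 5 GC bins and 74.2% in the highest, and within GC bins the exact adjusted p was 0.0254 for endoderm and 0.000236 for paraxial mesoderm.

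**Figure D1:**
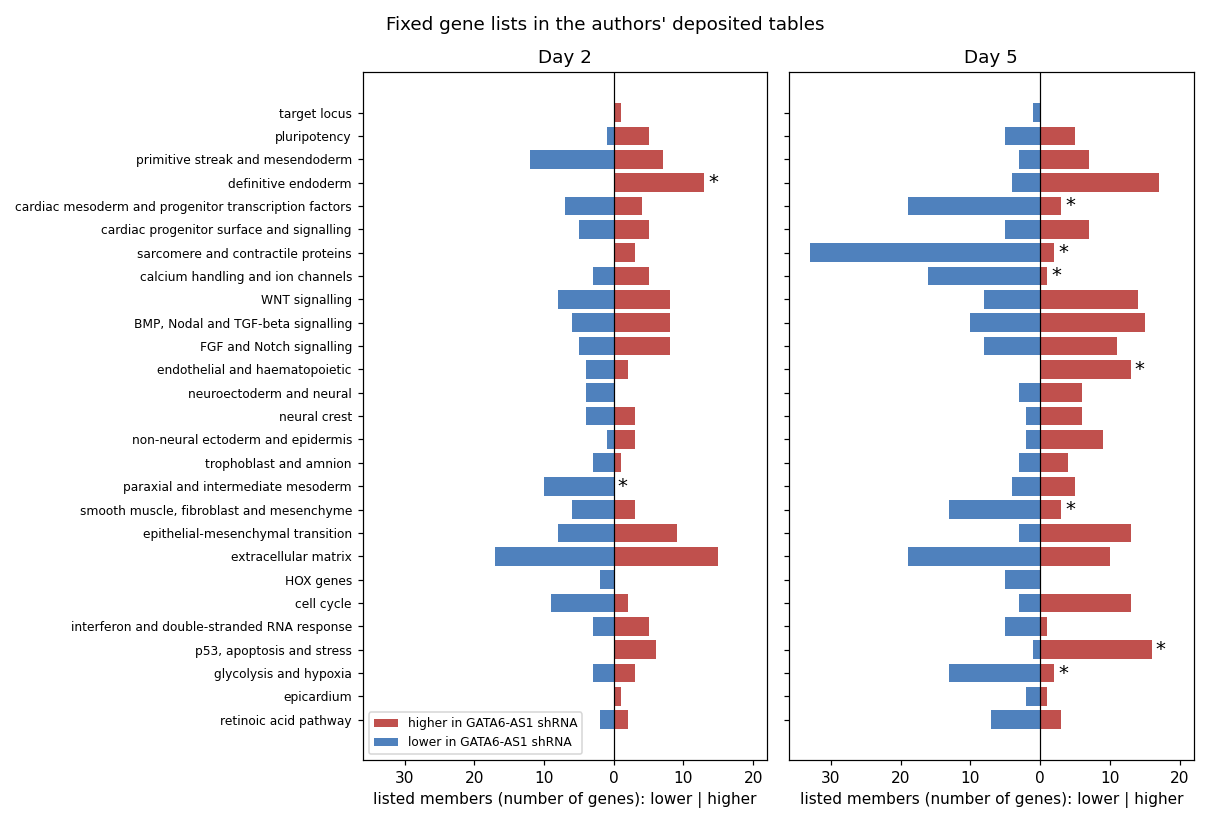
Number of listed members of each fixed gene list that were higher (right) or lower (left) in GATA6-AS1 shRNA cultures on day 2 and day 5, from the authors' deposited tables; an asterisk marks lists with a Fisher's exact adjusted p under 0.05. On day 5 the sarcomere list had 33 members lower and 2 higher.

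The second comparison asked the same question at day 5, when directed cardiac differentiation usually begins to express contractile genes. Cardiac muscle genes fell together in knockdown, whereas endothelial and stress-response genes rose together. MYH6, the atrial myosin heavy chain on chromosome 14, had a log2 difference of -10.74 and TNNT2, cardiac troponin T, had -7.43 in the authors' deposited table. SOX17, an endoderm and endothelial transcription factor, rose by 5.89 and the mesendoderm factor EOMES by 5.54 in the authors' deposited table. In all, 7172 genes were listed, 3951 higher and 3221 lower, and the largest p listed was 0.0128.

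Of 44 sarcomere and contractile protein genes, 33 fell and 2 rose, with a median log2 difference of -3.37 and an adjusted Fisher's exact p of 1.47e-08 over 25 lists. The Z-disc gene LDB3 was at -6.96, myosin binding protein C (MYBPC3) at -6.44 and SYNPO2L at -5.81 in the authors' deposited table. Calcium handling and ion channel genes followed, with 16 lower and 1 higher of 26 (median -2.52, adjusted Fisher's exact p = 0.000330). Phospholamban (PLN), the SERCA regulator, was at -5.81 and the ryanodine receptor RYR2 at -4.72 in the authors' deposited table. The 1 member that rose was GJA5, also an arterial endothelial connexin, at 4.33 in the authors' deposited table. Cardiac mesoderm and progenitor transcription factors had 19 lower and 3 higher of 36 (median -2.11, adjusted Fisher's exact p = 0.000900). TBX5, a first heart field factor, was at -5.59 and ZFPM2, a GATA cofactor, at -2.59 in the authors' deposited table. The muscle methyltransferase SMYD1 and the myosin chaperone UNC45B were at -7.03 and -6.99 in the authors' deposited table.

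Smooth muscle, fibroblast and mesenchyme genes had 13 lower and 3 higher of 30 (median -2.30, adjusted Fisher's exact p = 0.0155). Desmin (DES) was at -2.57 and smooth muscle myosin MYH11 at -3.01, against 3.05 for periostin (POSTN), in the authors' deposited table. Glycolysis and hypoxia genes had 13 lower and 2 higher of 29 (median -1.21, adjusted Fisher's exact p = 0.00500). The pyruvate dehydrogenase kinase gene PDK1 was at -3.67, aldolase C (ALDOC) at -2.54 and HK1 at -1.65 in the authors' deposited table.

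All 13 listed endothelial and haematopoietic genes of 36 rose, with a median of 2.44 and an adjusted Fisher's exact p of 0.00285. RUNX1, required for blood formation, was at 3.45, SOX18 at 2.68 and HHEX at 1.84 in the authors' deposited table. Stress and p53 genes had 16 higher and 1 lower of 29 (median 1.08, adjusted Fisher's exact p = 0.00428). The stress-response factor ATF4 was at 1.23, JUN at 1.02 and the BH3-only gene PMAIP1 (NOXA) at 1.71 in the authors' deposited table. Definitive endoderm genes had 17 higher and 4 lower of 27 (median 1.94), and the direction test stopped short of the threshold (adjusted Fisher's exact p = 0.0710). Besides SOX17, EPCAM was at 2.95 in the authors' deposited table. The endoderm factors HNF4A and FOXA2, picked after their values were seen, were at 4.08 and 4.04 in the authors' deposited table.

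Several other lists leaned 1 way without passing. The epithelial-mesenchymal transition list had 13 higher and 3 lower of 25 and cell cycle genes 13 higher and 3 lower of 30 (adjusted Fisher's exact p = 0.0896 for each). In the transition list the lean came from epithelial markers, 10 higher and none lower, while mesenchymal ones were 3 higher and 3 lower (Fisher's exact p between sides = 0.0357, split after the directions were seen). E-cadherin (CDH1) was at 2.71, CLDN7 at 2.78, the replication helicase gene MCM7 at 1.18 and TOP2A at -0.38 in the authors' deposited table. Extracellular matrix genes had 10 higher and 19 lower of 56 (adjusted Fisher's exact p = 0.0896), with collagen VI genes COL6A1 at -2.52 and COL6A2 at -2.48 in the authors' deposited table. All 5 listed HOX genes of 31 were lower (adjusted Fisher's exact p = 0.0570), among them the retinoic acid responsive HOXB1 at -4.72 in the authors' deposited table. Retinoic acid genes had 3 higher and 7 lower of 18, with DHRS3 at -2.36 and ALDH1A2 at -1.83 in the authors' deposited table. Interferon response genes had 1 higher and 5 lower of 27, with IFIT1 at -3.42 and BST2 at -2.06 in the authors' deposited table.

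WNT genes were 14 higher and 8 lower of 51, with the WNT target SP5 at 4.48, the feedback inhibitor NKD1 at 2.41 and the ligand WNT2 at -4.94 in the authors' deposited table. BMP, Nodal and TGF-beta genes were 15 higher and 10 lower of 40, with BMP10, a trabecular ligand, at -3.12 and MSX1, a BMP target, at 2.04 in the authors' deposited table. FGF and Notch genes were 11 higher and 8 lower of 36, with the Notch ligand JAG1 at -4.02 and FGFR4 at 3.37 in the authors' deposited table. Cardiac progenitor surface genes were 7 higher and 5 lower of 20, with BMP5 at -3.56 and the receptor KIT at 3.32 in the authors' deposited table. Primitive streak genes were 7 higher and 3 lower of 28 and pluripotency genes 5 higher and 5 lower of 22. TDGF1, a Nodal co-receptor with a near-identical processed copy that can share its reads, was at 5.11 in the authors' deposited table. Neural genes were 6 higher and 3 lower of 37, neural crest genes 6 higher and 2 lower of 15, and non-neural ectoderm genes 9 higher and 2 lower of 20. PAX3 was at -2.33 and SNAI2 at 1.48 in the authors' deposited table. Trophoblast genes were 4 higher and 3 lower of 23, paraxial and intermediate mesoderm genes 5 higher and 4 lower of 25, and epicardial genes 1 higher and 2 lower of 12. GATA3, a trophoblast and endothelial factor, was at 2.76 and LFNG, a Notch glycosyltransferase of the somite clock, at 2.81 in the authors' deposited table.

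The largest day 5 increases also included the cystatin CST1 at 7.34, the glutamate receptor GRIK3 at 5.96 and HHIP, a hedgehog antagonist, at 5.61 in the authors' deposited table. The largest decreases also included ASB2, a muscle ubiquitin ligase subunit, at -7.01 and BRINP2 at -7.00 in the authors' deposited table. By list mean against random lists, endoderm, primitive streak, non-neural ectoderm and the mixed transition list also passed as higher and HOX and interferon genes as lower (adjusted permutation p from 0.000208 to 0.0213). The non-neural ectoderm list shares epithelial markers with the transition list, so these are not separate results. Of the 384 list entries found on day 5, 383 passed when adjusted over the list alone and 290 when adjusted over all annotated genes. The count for the list alone was again nearly fixed in advance, because only genes with a p up to 0.0128 were listed. These entries hold 326 distinct genes. The mesenchyme and glycolysis calls ended among differences of at least 1 in size (adjusted Fisher's exact p = 0.117 and 0.118), where the endoderm and transition lists passed (0.00719 and 0.0162); with members of 1 list only mesenchyme failed and endoderm passed (0.537 and 0.0270). At a bound of 0.01 the calcium handling and mesenchyme calls ended (adjusted Fisher's exact p = 0.116 and 0.249), and the endothelial, stress and glycolysis lists had too few members for a call, as had the endothelial list at 0.05.

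The third comparison asked whether the same genes moved the same way on both days, which share no library. All 13 endoderm genes listed on both days were higher on day 2, and 11 of them were higher on day 5. Of all genes higher on day 2 and listed on both days, 62.7% were higher on day 5, and 85.9% of those at or above 2 in size on both days. Of those lower on day 2, 68.3% were higher on day 5, so over all shared genes the 62.7% shows no persistence. At or above 2 in size on both days this share was 19.4%. SCNN1A, an epithelial sodium channel subunit, was at 2.42 on day 2 and 4.04 on day 5 in the authors' deposited tables. TRDN went from 3.15 to -4.39, and NGFR from -4.29 to 2.37, in the authors' deposited tables. Of 1703 genes listed on both days, 606 were higher on both, 233 lower on both, 361 higher then lower and 503 lower then higher.

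Other genes higher on both days were the noncoding RNA DIO3OS (2.36 and 4.68), the protocadherin PCDH10 (2.18 and 3.70) and PPFIBP2 (3.28 and 3.76) in the authors' deposited tables. Lower on both were, among others, ANOS1 (-1.71 and -1.87), PPFIA2 (-3.33 and -3.64) and FAM13A (-2.55 and -1.20) in the authors' deposited tables. EGFLAM, a matrix protein gene, went from -1.84 to 3.51 and the integrin ITGA9 from -1.63 to 1.55 in the authors' deposited tables. The synaptotagmin SYT10 went from 2.49 to -2.81 and the phosphatase inhibitor PPP1R1A from 2.02 to -2.03 in the authors' deposited tables.

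Across the 1703 genes, 49.3% kept their direction, and Fisher's exact test gave an odds ratio of 0.778 for the same direction (p = 0.0159). Without 41 protein synthesis genes, picked after their directions were seen, the call ended (odds ratio 0.836, Fisher's exact p = 0.0869). Spearman's rho across these genes, which are not independent replicates, was 0.256 and Pearson's r was 0.303 (permutation p of rho = 1e-05, the smallest that 100000 permutations can give). Direction agreed more among large differences: 400 of 558 genes at or above 1 in size on both days kept it (71.7%, odds ratio 5.25, Fisher's exact p = 3.67e-17). At or above 2 in size it was 92 of 109 genes (84.4%). The Fisher's exact p-values here treat genes as independent too, so they are too small to an unknown degree.

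**Figure D2:**
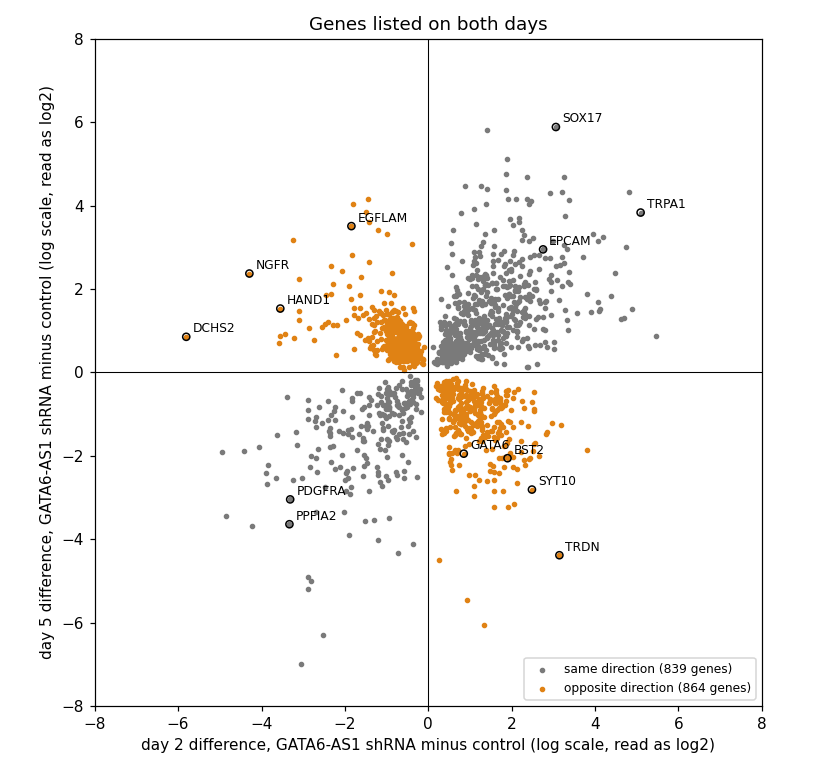
Difference on day 5 against difference on day 2 for the 1703 genes listed on both days, from the authors' deposited tables, each axis knockdown minus control on a log scale read as log2. Each point is a gene, grey for the 839 with the same direction and orange for the 864 with opposite directions, and the labelled genes are circled.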

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

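The tests of scaling, of small differences, of cell share, of endoderm-like cells and of developmental delay were chosen after the results were seen; the test for a reversed sign was written before.

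The authors' deposited tables listed 864 genes on both days in opposite directions, each at a larger p of at most 0.0128. Among the named genes these differences between days, day 5 minus day 2 in log2 units, were negative for TRDN (-7.53), SYT10 (-5.30), ZFPM2 (-4.17), PPP1R1A (-4.05), BST2 (-3.96), ENO3 (-3.81), TPM1 (-2.91), GATA6 (-2.80), MYO1D (-2.15), CDKN1C (-1.97), LTBP1 (-1.79), DDIT4 (-1.45) and TRAK1 (-1.28) in the authors' deposited tables. They were positive for NGFR (6.66), DCHS2 (6.66), EGFLAM (5.35), HAND1 (5.08), LFNG (4.65), SNAI2 (4.59), ERG (4.51), PAX2 (4.41), PDGFRB (3.31) and ITGA9 (3.18) in the authors' deposited tables. Smaller positive ones were ZFP42 (1.66), MCM4 (1.65), MCM2 (1.36), HNRNPAB (1.33) and SET (1.27) in the authors' deposited tables.

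For these opposite directions, a table with its sign reversed is argued against by genes at or above 2 in size on both days, of which 84.4% kept their direction (92 of 109, exact interval 76.2% to 90.6%). Small differences near the largest p are argued against as the whole source, since 28.3% of genes at or above 1 in size on both days still went opposite ways (158 of 558, exact interval 24.6% to 32.3%). The excess of opposite over same directions, however, was not seen at or above 1 in size. Both intervals treat genes as independent, so they are too narrow to an unknown degree. Scaling of the libraries on day 5 stays open: 66.7% of the genes listed with a difference under 0.5 in size were higher (1222 genes, exact interval 64.5% to 68.9%), and 64.9% without genes that share values, and without values per library a shift of all genes cannot be told apart from many small increases. A change of stage between the days, which the design names, stays open and untested.

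On day 5, 3 of the 4 cardiac lists fell (the surface and signalling list did not) while the endothelial list rose and endoderm genes were mostly higher. A lower share of cardiac cells that left all else alike stays open. Mesenchyme genes outside the cardiac lists were higher in 3 of 11 and endoderm genes in 17 of 19 (Fisher's exact p = 0.000974). Both directions had been seen before this test, and whether cardiac cells expressed these mesenchyme genes is unknown here. Without cardiac list genes, endothelial genes were higher in 13 of 13 and non-neural ectoderm genes in 9 of 11. Of the 20 non-neural ectoderm genes 9 stand in other lists too. Among them are CDH1, CLDN7 and EPCAM, epithelial markers of the transition list, so this share is not separate from the epithelial lean. Trophoblast genes were higher in 2 of 5 and HOX genes in 0 of 5. Whether knockdown cultures held more endoderm-like cells on both days stays open: 84.6% of the endoderm genes listed on both days were higher on both (11 of 13, exact interval 54.6% to 98.1%). Of all genes higher on day 2 and listed on both days 62.7% were higher on day 5, and 74.8% at size 1 or more on both days. The endoderm genes were not filtered by size, their directions had been seen before and the wide interval holds both shares. Of the 27 endoderm genes 9 stand in other lists too, among them the cardiac factors GATA6 and, named after its value was seen, GATA4, which both fell on day 5. A developmental delay stays open, because of the 12 streak genes lower on day 2 only 2, LHX1 and HAND1, named after their values were seen, were listed as higher on day 5 and the other 10 had no entry that day. Over the whole streak list, 7 of 10 listed on day 5 were higher, EOMES (5.54) among them, and 3 lower, which was not tested against a delay.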

How the results depend on the processing

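The adjusted p bound of 0.05, coding genes only, day 2's largest p on day 5, the 5 GC bins and leaving out genes that share values or protein synthesis families, and the split of the transition list, were chosen after the data were seen; the others were planned. The bounds over all annotated genes are stricter than the authors' listing. With the bound at 0.05, 0.01 and 0.001 the day 2 count of 3592 became 1784, 149 and 0, the day 5 count of 7172 became 4515, 911 and 5, and the shared count of 1703 became 661, 13 and 0. At the unadjusted p listed by the authors, all 3592 and 7172 stand. At a minimum size of 1 the counts were 1585, 2623 and 558. The share higher moved from 58.0% to 79.2% on day 2 at a bound of 0.01 (118 higher, 31 lower) and to 68.5% at size 1 (1086 and 499), and on day 5 from 55.1% to 44.5% at size 1 (1166 and 1457). The odds ratio for the same direction on both days, 0.778, reversed to 1.14 at a bound of 0.05, 4.67 at 0.01 and 5.25 at size 1 (Fisher's exact p = 0.454, 0.510 and 3.67e-17); it stayed below 1 with coding genes only, with day 2's largest p and within GC bins (0.743, 0.737 and 0.761) and without genes sharing values (0.762). Without 41 genes of the protein synthesis families, which were picked after their opposite directions were seen, it was 0.836 and no longer passed (Fisher's exact p = 0.0869). The cause was not tested. GATA6 went from 0.85 to -1.95 in the other day's authors' deposited table. Of the lists, 2 passed on day 2, against 0 at a bound of 0.01, 1 at 0.05, 1 with members of 1 list only (cell cycle, with endoderm and paraxial mesoderm lost) and 8 by list mean against random lists. On day 5, 7 passed, against 2 at a bound of 0.01 and 13 by list mean. The bound of 0.01 ended the calcium handling and mesenchyme calls (Fisher's exact adjusted p = 0.116 and 0.249) and left endothelial, stress and glycolysis lists with under 4 members. At size 1 the mesenchyme and glycolysis calls ended and the endoderm and transition lists passed (Fisher's exact adjusted p = 0.00719 and 0.0162), and with members of 1 list only mesenchyme was lost and endoderm passed (0.0270). The list mean lost none and added 6 lists on each day. On day 2 these were lower: primitive streak (adjusted permutation p = 0.000383, the smallest possible here), cardiac mesoderm factors (0.00115), neural crest (0.0200), WNT (0.0276), mesenchyme (0.0307) and trophoblast (0.0418). On day 5 endoderm (adjusted permutation p = 0.000208, the smallest possible here), primitive streak (0.000536), the transition list, which mixes epithelial and mesenchymal markers, (0.00125) and non-neural ectoderm (0.00352) were higher, and HOX (0.00109) and interferon genes (0.0213) lower. Primitive streak on day 2 also passed at size 1 (Fisher's exact adjusted p = 0.0197). Within GC bins no list was lost, and HOX genes were gained on day 5 (exact adjusted p = 0.0412). Without genes sharing values none was lost, and endoderm passed on day 5 (Fisher's exact adjusted p = 0.0469). Both day 2 losses at a bound of 0.01 were lists left with under 4 members. Of 181 named values, 174 passed a bound of 0.05, 81 passed 0.01 and 0 passed 0.001; DDIT4, ENO3, IGFBP5, RARG and TNNT1 on day 2 and LRRN4 and SEMA3D on day 5 failed at 0.05. No paired analysis was possible because the tables analysed hold no values per library. For the same reason leaving out replicates, minimum mean counts, other count tools, a low-count filter and a pseudocount were not run, and what depth limits is unknown.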

Other observations

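The symbol families, the comparison of GC bins on day 5, the test of chromosomes 17 and 19 on day 5 and both tests within GC bins were chosen after the results were seen; the test of the GATA6 neighbourhood was written before its result.

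Several symbol families tied to protein synthesis leaned lower on day 2 and higher on day 5, by small amounts. The families were picked from 32 looked at, after the directions were seen, so their p-values describe the lean and are no independent test. Families were formed by the start of the symbol, so some members have other roles. Translation initiation factors were 16 of 16 lower on day 2 and 25 of 30 higher on day 5 (Fisher's exact adjusted p = 1.06e-05 and 0.00466). The tRNA synthetases were 10 of 10 lower and then 20 of 21 higher (Fisher's exact adjusted p = 0.00133 and 0.000506), and cytoplasmic ribosomal proteins 6 of 6 lower and then 33 of 34 higher (Fisher's exact adjusted p = 0.0186 and 1.85e-06). Mitochondrial ribosomal proteins did not pass on day 2, with 7 of 9 lower (Fisher's exact adjusted p = 0.121), and were 27 of 29 higher on day 5 (Fisher's exact adjusted p = 0.000141). Proteasome subunits, which degrade tagged proteins, were 21 of 21 higher on day 5 (Fisher's exact adjusted p = 7.54e-05). The lean was not limited to protein synthesis. Nucleoporins were 8 of 9 lower and then 18 of 19 higher (Fisher's exact adjusted p = 0.0186 and 0.00136). DEAD and DEAH box helicases were 10 of 11 lower and then 22 of 25 higher (Fisher's exact adjusted p = 0.00544 and 0.00316). Of all genes listed under 0.5 in size, 45.2% were higher on day 2 and 66.7% on day 5. Among all listed genes these shares were 58.0% and 55.1%, so genes with small differences leaned the same ways as these families. Scaling, left open above for day 5 and not tested for day 2, cannot be told apart here.

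All 18 histone genes listed on day 2 were lower (median -0.70, Fisher's exact adjusted p = 3.67e-06), while 5 of 7 were higher on day 5. Most histone messages carry no polyA tail, so a polyA library samples them incompletely. Zinc finger genes named ZNF were higher on day 5 in 96 of 133 (Fisher's exact adjusted p = 0.000499). Transcripts named LINC were lower in 9 of 9 and antisense transcripts named AS in 20 of 28 on day 5 (Fisher's exact adjusted p = 0.00316 and 0.0188). On day 2 they were higher in 7 of 9 and 6 of 9, without passing (Fisher's exact adjusted p = 0.450 and 0.775).

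On day 2, genes of chromosomes 17 and 19 were more often higher than those of other autosomes, in 68.2% and 70.9% (Fisher's exact adjusted p = 0.0184 and 0.00404). A gain of these chromosomes in the knockdown arm stays open: their odds ratio on day 5 was 1.06, with an interval of 0.908 to 1.24 that allows a lean either way, and they were picked as the most skewed of 22 autosomes on day 2. GC content may account for the lean and stays open: within 5 GC bins none of the 22 autosomes passed on day 2, and the smaller exact adjusted p of chromosomes 17 and 19 was 0.773. Together these 2 chromosomes had an odds ratio of 1.85 that went to 1.37 within bins (3017 coding genes, 95% interval 1.06 to 1.77), but they had been picked on the same day 2 values, so this does not rule GC out. On day 5, 51.5% of the lowest and 53.7% of the highest GC bin were higher.

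As a hypothesis, knockdown of GATA6-AS1 may act on genes near its own locus. Of 9 coding genes within 1 Mb of GATA6, 2 were listed on day 2 and 5 on day 5, against 60 and 75 of 256 elsewhere on chromosome 18, and the smaller Fisher's exact p was 0.134, which leaves it open. The listed neighbours, named after their values were seen, were GREB1L (-2.75) and SNRPD1 (-0.71) on day 2 in the authors' deposited table. On day 5 they were CABLES1 (1.21), SNRPD1 (0.88), GREB1L (0.78), ESCO1 (0.18) and MIB1 (-0.33) in the authors' deposited table.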
